A study of Sorghum bicolor with 18 samples.

How the data were processed

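RNA of axillary buds of sorghum cultivar 100M was measured in 18 libraries, 3 for each of 6 groups: intact or leaf-removed plants, 1, 3 and 6 h after treatment. Per the labels, buds were pooled by 15, RNA was extracted with Trizol, treated with DNase and cleaned on RNeasy columns, libraries were made with TruSeq chemistry and sequenced on an Illumina HiSeq. Replicate letters name separate pools, so the replicates measure variation between pools and not between single plants.

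The deposited table gives, for each gene and library, a count of total exon reads, of unique exon reads and of intron reads, and an RPKM. The authors' RPKM values followed from the deposited counts and exon lengths with 1 constant per library, solved from the RPKM values. The total exon reads were 88.0% to 92.8% of that constant, and RPKM was not used in the tests. For each time the authors give a signed fold change of leaf-removed over intact buds and an FDR-corrected p-value from their own test with tagwise dispersions. The aligner, its version and the genome build were not given in the sources used here. The table holds 34211 sorghum genes, of which 25851 have an Arabidopsis locus, 11243 a symbol and 23860 a title; these annotations were the only source of gene names. None of the identifiers (0) matched the reference table of RefSeq names, so positions and base composition were not used here.

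Total exon reads were tested with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, with TMM factors, the default expression filter and one fit of 6 groups with 12 residual degrees of freedom. It left 21852 genes, with a biological coefficient of variation of 24.9%. Leaf-removed was compared with intact at each time, the effects were compared between times by interaction contrasts, and intact buds were compared across the 3 times with an F test. Benjamini-Hochberg adjusted p under 0.05 over all tested genes was called. Gene lists were tested with camera (limma 3.58.1, preset correlation of 0.01, at least 5 tested members), with camera at an estimated correlation and with fry, and adjusted over the lists and times. The 33 lists were fixed from annotation words before the data were examined, and 7 narrower lists were added after the annotation was seen. The added lists were adjusted among themselves only. Their adjusted p rest on fewer tests than those of the fixed lists and cannot be compared with them directly. Counts adjusted over the list alone used only the p-values of its members. Log2 CPM (counts scaled to a library size of 1e6) used a prior count of 2. Principal components, deviations from group means and figures used numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 under Python 3.11.15.

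Named genes were chosen by a rule fixed with the lists. Per time it took the 8 highest and 8 lowest folds among annotated genes that were called, whose 3 and 3 values did not overlap, with at least 10 reads in the lower group and a mean of at least 5 CPM in the higher group. It also took up to 3 members per list and time by p, and, whatever their result, genes annotated BRANCHED1, TEOSINTE BRANCHED 1, dormancy-associated or NCED, and the JAZ genes by count. Small families counted within a list, such as the MCM genes, were chosen after their values were seen.

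In M (1e6 reads), exon reads per library ranged from 21.4 to 45.8, 97.0% to 97.6% of them unique, and intron reads were 3.12% to 7.23% of gene reads. Reads without molecular identifiers are not independent molecules, so read counts give counting error only. The tests were tried on simulated data made from these libraries with changes of 1.5-fold, 2-fold and 4-fold. Alternatives were DESeq2 1.42.0 and its size factors, library totals, no filter and a stricter one of 1 CPM in 9 libraries, voom, a replicate block over all times and within each time, the 6 libraries of each time alone, a minimum of 2-fold, and each library left out in turn. Chosen after seeing the data were unique reads, leaving out the 5 libraries that deviate alike, and the intron share as a covariate. Whether a replicate letter links an intact and a leaf-removed library is not stated in the sources used here. Deviations of libraries with the same letter correlated by -0.405 to 0.528 within times, and no pairing was used in the main test. No library was left out of it.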

Results

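Axillary buds of sorghum (Sorghum bicolor, cultivar 100M) were sequenced 7 days after sowing, with the coleoptile and the overlying leaf peeled off the culm or left in place. Collection was at 1, 3 and 6 h, from treated and from intact plants alike. This gave 6 groups of 3 libraries and 18 libraries in all. Each library came from a pool of 15 buds, and the labels state that the 3 pools of best RNA quality out of 4 were sequenced per group. Exon reads per library ranged from 21.4 to 45.8 M, with a median of 28.7 M, and 22543 to 25413 genes had reads. The main test covered 21852 of the 34211 genes in the table. Gene names below are those of the matched Arabidopsis gene that the deposited table gives beside each sorghum identifier, and genome build and positions were not given in the sources used here. Values written with ± are log2 fold changes of leaf-removed over intact buds with their standard error, from 3 libraries against 3, unless another unit is named.

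Leaf removal changed 10684 of 21852 genes at 1 h, 7420 at 3 h and 7421 at 6 h (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 5423 were higher and 5261 lower at 1 h, 3889 and 3531 at 3 h, and 3943 and 3478 at 6 h. Changes of at least 2-fold were found for 5749, 3334 and 2990 genes. Component 1 of a principal component analysis held 46.7% of the variance and ran from intact libraries (-80.5 to -48.8) through leaf-removed libraries at 6 h (-4.77 to 24.5) and 3 h (22.0 to 76.6) to leaf-removed libraries at 1 h (115 to 150.5). With library totals in place of TMM factors the median of all tested genes shifted from -0.01 to -0.25 at 1 h, from 0.00 to -0.12 at 3 h and from -0.03 to -0.21 at 6 h. Under that scaling 36.5%, 40.6% and 33.1% of the calls were higher, against 50.8%, 52.4% and 53.1%. All directions below are relative to the TMM scale.

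**Figure D1:**
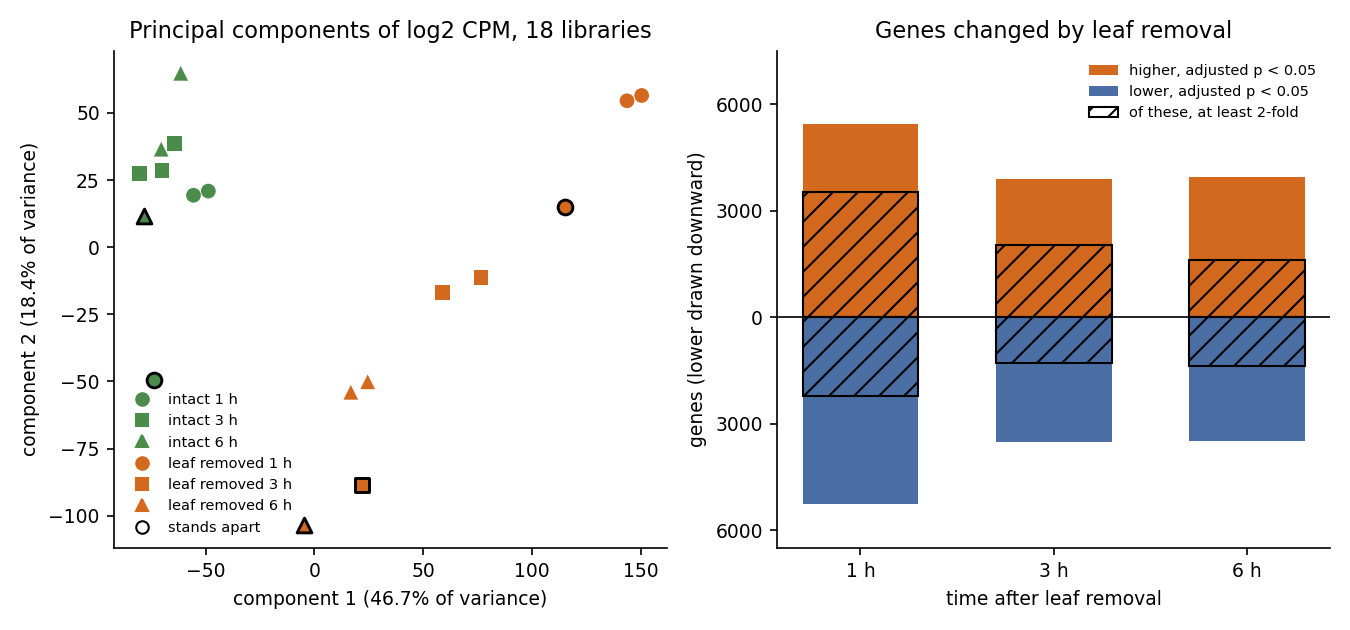
Left, scores of the 18 libraries on components 1 and 2 of log2 CPM, by treatment and time, with the 5 libraries that deviate alike from their groups outlined in black. Right, numbers of genes higher (upward) and lower (downward) in leaf-removed than in intact buds at each time, of which the hatched part changed at least 2-fold; the number was 10684 at 1 h, 7420 at 3 h and 7421 at 6 h.

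In 5 libraries the values deviated from their own group in the same way: intact 1 h replicate c, intact 6 h replicate d, and leaf-removed 1 h replicate d, 3 h replicate b and 6 h replicate d. This shared deviation held 49.9% of the variance within groups, and the 5 libraries had intron shares of 4.65% to 7.23% of gene reads against 3.12% to 4.82% in the other 13. Intron shares also differed between the compared groups, with means of 5.33% in intact and 3.86% in leaf-removed buds at 1 h, 4.64% and 4.02% at 3 h, and 3.83% and 3.96% at 6 h. With the intron share as a covariate 11985, 10520 and 10713 genes were called at the 3 times. Histone genes lay lower in these 5 libraries (mean of the medians -0.75 log2 units from the group mean), as did light-harvesting genes (-0.59), gibberellin genes (-0.57), aquaporins (-0.54), wall-loosening genes (-0.50), phenylpropanoid genes (-0.49), jasmonate biosynthesis genes (-0.46) and defence genes (-0.44). Most other lists lay lower in these libraries too, while chromatin (0.17) and clock genes (0.10) lay higher in all 5. Without the 5 libraries 11873, 10346 and 9273 genes were called at 1, 3 and 6 h. Markers of leaf tissue gave no list call at any time. The secondary wall list, a marker of stem or vascular tissue, was called at 1 h, with values given below. Of 67 photosynthesis genes 9 were higher and 4 lower at 1 h (camera adjusted p = 0.32, adjusted p = 0.97 with an estimated correlation), 8 and 9 at 3 h (camera adjusted p = 0.48), and 12 and 3 at 6 h (camera adjusted p = 0.49), with 9 and 2, 8 and 9, and 9 and 0 adjusted over the list alone. Without the 5 libraries 12 and 12 of 65 were called at 1 h, 8 and 10 at 3 h, and 11 and 6 at 6 h. Of 36 genes named for C4 enzymes 8, 9 and 11 were higher and 2, 5 and 7 lower (camera adjusted p = 0.33, 0.52 and 0.54). Of 34 cuticle genes 9, 8 and 4 were higher and 12, 4 and 3 lower (camera adjusted p = 0.65, 0.27 and 0.83). Adjusted over the list alone, these counts were 8, 9 and 11 with 1, 5 and 7 for C4 enzymes and 9, 9 and 4 with 13, 4 and 3 for cuticle genes.

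The comparison at 1 h asked which genes responded first once the leaf was gone. Within 1 h, more genes of jasmonate synthesis and signalling, abscisic acid response, calcium and touch, WRKY and defence rose than fell in the exposed buds. The calls on these lists were lost with an estimated correlation (adjusted p = 0.36 to 0.71). Over the same hour all 13 MCM genes of DNA replication and 9 of 11 A-type response regulators of cytokinin fell, with MCM4, MCM6 and ARR3 at less than 10% of the intact level. Among the genes with the highest folds were a pair of alpha/beta-hydrolases, a sterol demethylase homologue, a RING finger protein and a caleosin. The BRANCHED1-annotated genes went in opposite directions, and all 4 dormancy-associated genes rose at this time point.

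Genes of jasmonate, a hormone of wound responses, rose at 1 h. Of 25 tested genes for its biosynthesis 18 rose and none fell, also when adjusted over the list alone (camera adjusted p = 2.0e-06, adjusted p = 0.64 with an estimated correlation). OPR3 (Sobic.007G151100), whose Arabidopsis counterpart reduces the jasmonate precursor, rose by 2.78 ± 0.20 (adjusted p = 2.0e-08), and 3 of 4 genes for allene oxide synthase and cyclase rose. Many of the members that rose belong to related branches of oxylipin metabolism: 6 of 8 genes annotated LOX1 or LOX5, which are 9-lipoxygenases in Arabidopsis, and 4 of 8 annotated OPR1 or OPR2, which are not the jasmonate-forming isoform. The LOX1-annotated Sobic.003G385500 was the gene with the most reads in every leaf-removed group, with 1.74% of all exon reads at 3 h, and at 1 h it rose by 2.86 ± 0.31. A further LOX1 gene, Sobic.001G125700, rose by 5.26 ± 0.44, and OPR2 (Sobic.010G084700) by 8.72 ± 0.70 from 20 reads in the 3 intact libraries. Of 30 jasmonate signalling genes 22 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 9.2e-08, adjusted p = 0.40 with an estimated correlation). Among the 15 JAZ genes, the jasmonate-responsive repressors, 14 rose, for example JAZ1 (Sobic.001G482700) by 6.42 ± 0.42 and JAZ2 (Sobic.002G374100) by 0.91 ± 0.13. The JAZ list was drawn up after the annotation was seen and adjusted with the other added lists only (camera adjusted p = 6.6e-10, adjusted p = 0.052 with an estimated correlation). The gene that fell was annotated COI1 (Sobic.003G359600), the jasmonate receptor, at -0.70 ± 0.13. JAR1 (Sobic.009G249900), a GH3 gene whose Arabidopsis counterpart conjugates jasmonate, rose by 1.59 ± 0.10, with only 55.5% of its reads placed uniquely.

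Genes of abscisic acid, a hormone of drought response and bud dormancy, rose at 1 h as well. Of 83 response genes 45 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 3.1e-07, adjusted p = 0.64 with an estimated correlation). They included a dehydrin (Sobic.001G149500) at 5.56 ± 0.26 and the phosphatase gene HAB1 (Sobic.009G213000) at 2.90 ± 0.17. Not all members act in abscisic acid signalling: 24 genes of that list are LEA hydroxyproline-rich glycoproteins, a family that includes membrane proteins of pathogen response, and 9 of them rose while 2 fell. A narrower list, drawn up after the annotation was seen, kept 26 phosphatases, receptors, AFP proteins and dehydrins, of which 21 rose and none fell (camera adjusted p = 4.9e-11; adjusted p = 0.089 with an estimated correlation). All 5 genes annotated PYL6 rose, among them Sobic.001G400700 at 7.98 ± 0.58 with 86.1% of reads placed uniquely; the fold family of that receptor also holds pathogenesis-related PR-10 proteins. Of 9 genes for synthesis and breakdown of the hormone 4 rose and none fell, 6 and 2 adjusted over the list alone (camera adjusted p = 0.081, adjusted p = 0.48 with an estimated correlation). The breakdown gene CYP707A4 (Sobic.002G225400) went from 3.29 ± 1.30 to 138 ± 5.04 CPM (mean ± SD, n = 3), a fold of 41.9 (adjusted p = 9.5e-10). On the synthesis side, the epoxidase gene ZEP (Sobic.006G097500) rose by 1.74 ± 0.12. A pair of genes annotated NCED9, an enzyme of the committed step, rose by 3.19 ± 0.73 (Sobic.001G155300, adjusted p = 0.0019) and 3.74 ± 1.09 (Sobic.002G037400, adjusted p = 0.0095, 5 reads in the 3 intact libraries). Other cleavage dioxygenases did not pass: CCD1 (Sobic.001G509200) had 0.55 ± 0.25, a further CCD1 (Sobic.010G050300) -1.01 ± 0.45 and CCD4 (Sobic.004G268500) 0.47 ± 0.69.

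The lists of calcium, WRKY, defence and phenolic genes held more genes that rose than fell at 1 h. Of 71 genes named for calmodulin, calcium or touch 38 rose and 9 fell, 39 and 10 adjusted over the list alone (camera adjusted p = 0.00024, adjusted p = 0.36 with an estimated correlation). CAM1 (Sobic.001G094400) had 3.18 ± 0.23, CAM5 (Sobic.002G424350) 2.25 ± 0.16 and a calmodulin-binding transcription regulator (Sobic.002G306000) 2.34 ± 0.16. Of 65 WRKY transcription factor genes 36 rose and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.0018, adjusted p = 0.69 with an estimated correlation). WRKY28 (Sobic.009G247300) rose by 7.28 ± 0.55. Of 72 defence genes, which are mainly chitinases, thaumatin-like proteins and protease inhibitors, 34 rose and 4 fell, 36 and 4 adjusted over the list alone (camera adjusted p = 0.00012, adjusted p = 0.71 with an estimated correlation), with a potato-type protease inhibitor (Sobic.009G009800) at 6.38 ± 0.51 and a chitinase (Sobic.006G132300) at 2.54 ± 0.46. Of 39 phenylpropanoid genes, which make lignin and related phenolics, 25 rose and 1 fell, 26 and 1 adjusted over the list alone (camera adjusted p = 1.0e-05, adjusted p = 0.68 with an estimated correlation). HCT (Sobic.003G068300) rose by 8.45 ± 0.38 from 20 reads in the intact group, and CAD9 (Sobic.007G076000) by 5.54 ± 0.49. Of 155 genes for peroxidases and glutathione transferases 69 rose and 9 fell, also when adjusted over the list alone (camera adjusted p = 8.9e-05, adjusted p = 0.71 with an estimated correlation). GSTL3 (Sobic.002G421200) rose by 2.74 ± 0.13. Of 35 secondary wall genes 21 rose and 1 fell, 22 and 2 adjusted over the list alone (camera adjusted p = 0.0015, adjusted p = 0.68 with an estimated correlation), and without leaf-removed 1 h replicate b 13 rose. Secondary wall genes were also fixed as a marker of stem or vascular tissue. Whether the share of such tissue differed between the groups was not tested.

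Cytokinin genes fell at 1 h. Of 24 tested genes 13 fell and 3 rose, also when adjusted over the list alone (camera adjusted p = 0.002, adjusted p = 0.68 with an estimated correlation). Those that fell were 9 of 11 A-type response regulators, which are induced by cytokinin, 3 of 6 oxidases that degrade it and 1 of 6 isopentenyltransferases that make it. ARR3 (Sobic.004G178000) fell to 6.91% of the intact level (-3.86 ± 0.32, adjusted p = 1.1e-07), and CKX1 (Sobic.003G421100) to 3.42% (-4.87 ± 0.24), while CKX5 (Sobic.003G313800) rose by 5.25 ± 0.53. Of 13 gibberellin metabolism genes 7 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.017, adjusted p = 0.71 with an estimated correlation). Of the 7, 6 were among the 10 gibberellin 2-oxidases, enzymes that inactivate the hormone. GA2OX2 (Sobic.009G196300) rose by 7.03 ± 0.59 and GA2OX8 (Sobic.006G150800) by 5.10 ± 0.34. Among 4 genes for ethylene-forming ACC oxidase, a list too short for the list test, 1 rose and 1 fell, also when adjusted over the list alone. They were both annotated ACO4, Sobic.004G313100 at 2.24 ± 0.35 and Sobic.002G221900 at -2.49 ± 0.34. Auxin response genes went both ways, 21 of 81 higher and 33 lower, 22 and 33 adjusted over the list alone (camera adjusted p = 0.14, adjusted p = 0.89 with an estimated correlation). GH3.2 (Sobic.001G331200), which conjugates auxin, had -4.27 ± 0.66, and ARF7 (Sobic.004G037800) had -1.91 ± 0.15. Of 19 auxin transport genes 4 were higher and 5 lower, also when adjusted over the list alone (camera adjusted p = 0.79, adjusted p = 0.97 with an estimated correlation), with PIN4 (Sobic.005G025900), an efflux carrier, at -2.94 ± 0.29.

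Genes tied to bud outgrowth were followed whatever their result. BRANCHED1 restrains axillary bud growth, and the 2 genes with that annotation differed. Sobic.002G198400 went from 6.78 ± 0.845 to 3.19 ± 0.233 CPM (mean ± SD, n = 3), a log2 fold change of -1.09 ± 0.18 (adjusted p = 0.00014). Sobic.007G135700, with 131 reads against 50 in 3 libraries each, had 1.83 ± 0.59 (adjusted p = 0.017). The second call was lost without intact 1 h replicate c (adjusted p = 0.068) and without leaf-removed 1 h replicate c (adjusted p = 0.070). Of the 12 genes in the branching list 4 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.78, adjusted p = 0.97 with an estimated correlation); most members are other TCP family genes rather than known branching genes. TCP5 (Sobic.009G195000) rose by 1.82 ± 0.24 and MAX2 (Sobic.010G043000), the strigolactone receptor component, by 1.04 ± 0.15. The 4 genes annotated dormancy/auxin associated, markers of arrested buds in other plants, all rose, also when adjusted over the list alone: Sobic.002G213800 by 2.11 ± 0.34, Sobic.001G191200 by 1.27 ± 0.27, Sobic.007G148200 by 0.89 ± 0.22 and Sobic.001G377000 by 0.83 ± 0.25. The call on Sobic.001G377000 was lost without intact 1 h replicate c (adjusted p = 0.056) and without leaf-removed 1 h replicates b or c (adjusted p = 0.091 and 0.054). The list is too short for the list test.

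Replication and chromatin genes fell sharply at 1 h. Of 53 cell cycle genes 31 fell and 5 rose, 32 and 5 adjusted over the list alone (camera adjusted p = 2.7e-07; adjusted p = 0.047 with an estimated correlation). All 13 genes for MCM subunits, the replicative helicase, fell, with a median of -1.88: MCM4 (Sobic.003G183700) had -3.37 ± 0.14 (adjusted p = 1.0e-10), MCM6 (Sobic.009G087000) -3.34 ± 0.17 and MCM5 (Sobic.004G331600) -2.97 ± 0.14. ETG1 (Sobic.003G055600), a replisome factor, fell from 192 ± 29.2 to 12.04 ± 0.821 CPM (mean ± SD, n = 3; log2 fold change -3.999 ± 0.16, adjusted p = 8.1e-11). The S-phase cyclin CYCA3;1 (Sobic.001G169800) had -2.52 ± 0.14, whereas of 5 B-type cyclins, which act in mitosis, 1 fell and 1 rose. Of 102 chromatin genes 59 fell and 6 rose, 61 and 7 adjusted over the list alone (camera adjusted p = 8.3e-08, adjusted p = 0.68 with an estimated correlation). Examples were a jumonji factor (Sobic.001G175000) at -3.57 ± 0.17, the remodeller DDM1 (Sobic.002G021200) at -2.19 ± 0.11, and the silencing genes CMT3 (Sobic.006G214000) at -1.16 ± 0.17 and AGO4 (Sobic.003G129500) at -1.12 ± 0.15. Of 52 histone genes 3 were higher and 1 lower, 3 and 0 adjusted over the list alone (camera adjusted p = 0.62, adjusted p = 0.97 with an estimated correlation), and with library totals as scaling 3 higher and 5 lower. Without the 5 libraries that deviate alike 14 were higher and 5 lower. Of 289 cytosolic ribosomal protein genes 9 were higher and 48 lower, 6 and 37 adjusted over the list alone (camera adjusted p = 0.27, adjusted p = 0.97 with an estimated correlation). That list takes every gene annotated as ribosomal protein without an organelle name, so some members may not be cytosolic.

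Genes of sugar use, water transport and the clock rose at 1 h, as did the early light-induced genes. Of 52 sugar use genes 27 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.0019, adjusted p = 0.68 with an estimated correlation), including 8 of 10 trehalose-phosphate synthases. TPS7 (Sobic.003G296000) rose by 2.10 ± 0.15 and the cell wall invertase CWINV2 (Sobic.004G166700) by 2.17 ± 0.30. That list also holds invertase and pectin methylesterase inhibitors. Of 17 aquaporins 11 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.019, adjusted p = 0.75 with an estimated correlation). TIP4;1 (Sobic.009G085900) rose by 4.12 ± 0.35. Of 12 clock genes 7 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.015, adjusted p = 0.64 with an estimated correlation). TOC1 (Sobic.004G216700) had 1.68 ± 0.20 and ELF3 (Sobic.009G257300) 1.49 ± 0.16. Both early light-induced genes, which protect chloroplasts under excess light, rose, also when adjusted over the list alone. Sobic.002G052000 rose by 3.96 ± 0.53, and Sobic.002G052100 had 2442 reads against 2 in the intact group. Among genes linked to carbon starvation 4 of 15 rose and 5 fell, 4 and 6 adjusted over the list alone (camera adjusted p = 0.94, adjusted p = 0.97 with an estimated correlation). SEN1/DIN1 (Sobic.010G270300) rose by 3.19 ± 0.25 and the asparagine synthetase ASN1 (Sobic.001G406800) by 2.01 ± 0.44, while PS3 (Sobic.006G173000), a phosphate starvation gene that the list also holds, had -3.50 ± 0.52.

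Among the highest folds at 1 h were those of an alpha/beta-hydrolase (Sobic.010G160033) at 10.32 ± 0.69, the sterol demethylase homologue CYP51G1 (Sobic.002G342400) at 9.80 ± 0.58, a RING finger protein (Sobic.006G005500) at 8.83 ± 0.44, a caleosin (Sobic.010G105000) at 8.61 ± 0.43 and a second hydrolase (Sobic.010G159900) at 8.52 ± 0.70. The hydrolase pair share reads, with 47.02% and 35.9% placed uniquely, so their separate values are uncertain. A mannose-binding lectin (Sobic.002G093700) rose by 8.44 ± 0.25 and had the smallest adjusted p of the named genes (2.8e-12). HSP70 (Sobic.001G420100) rose by 5.97 ± 0.40, although of 166 heat shock and chaperone genes 53 were higher and 40 lower, 55 and 40 adjusted over the list alone (camera adjusted p = 0.38, adjusted p = 0.84 with an estimated correlation). Flavonoid genes (6 higher and 1 lower of 17; camera adjusted p = 0.082, adjusted p = 0.69 with an estimated correlation), wall-loosening genes (14 and 12 of 55; median -0.11, mean 0.11; camera adjusted p = 0.83, adjusted p = 0.97 with an estimated correlation) and homeobox genes of the meristem (5 and 4 of 16; camera adjusted p = 0.71, adjusted p = 0.97 with an estimated correlation) gave no list call, and adjusted over the list alone these were 6 and 1, 14 and 12, and 5 and 5. Auxin response, ribosomal protein and carbon starvation genes had no list call either. With library totals as scaling the median at 1 h turned from 0.20 to -0.02 for branching, from 0.22 to -0.02 for carbon starvation, from 0.14 to -0.11 for photosynthesis, from 0.11 to -0.13 for C4 enzyme and from 0.19 to -0.06 for meristem genes. Heat shock genes became 40 higher and 48 lower. Only the cell cycle call at 1 h stayed under 0.05 among all fixed lists and times with an estimated correlation. It too was lost with that correlation under the replicate block (adjusted p = 0.18).

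**Figure D2:**
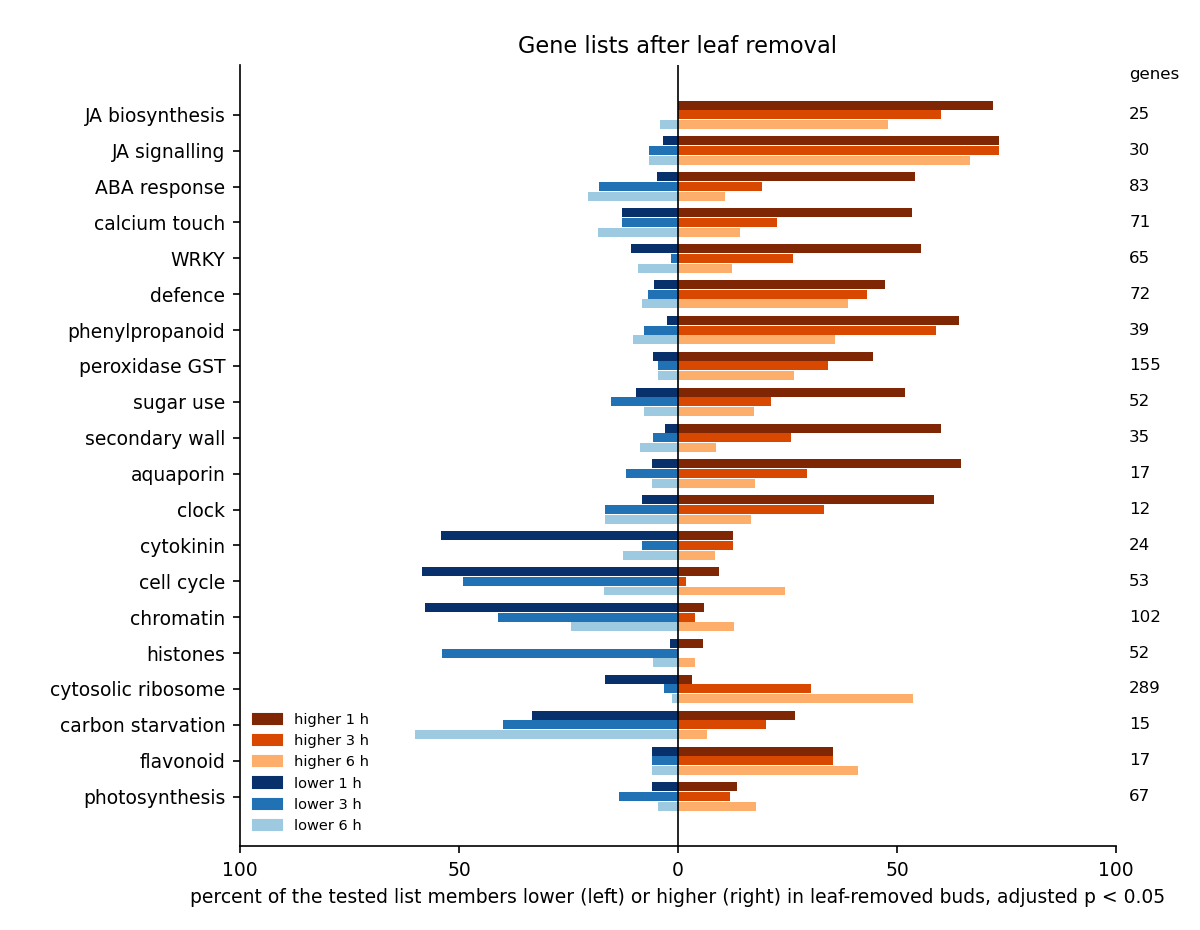
Percent of the tested members of 20 fixed gene lists that were higher (right) or lower (left) in leaf-removed buds at adjusted p under 0.05, with bars for 1, 3 and 6 h from dark to light and the number of tested genes at the right edge. Cell cycle genes were lower in 31 and 26 of 53 at 1 h and 3 h, and cytosolic ribosomal protein genes were higher in 155 of 289 at 6 h.

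The comparison at 3 h showed a narrower response, in which more jasmonate and defence genes were higher than lower, 7 of 13 MCM genes were still lower and all 5 B-type cyclins fell. Of the histone genes 28 of 52 were lower, and more ribosomal protein genes were higher than lower. The calls on the jasmonate, defence, histone and ribosomal protein lists at 3 h were lost with an estimated correlation (adjusted p = 0.32 to 0.78). The dormancy-associated genes, which had been above intact buds at 1 h, now lay below them.

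Of 25 jasmonate biosynthesis genes 15 rose and none fell at 3 h, also when adjusted over the list alone (camera adjusted p = 4.8e-05, adjusted p = 0.68 with an estimated correlation). OPR2 had 6.79 ± 0.70, LOX1 (Sobic.003G385500) 3.10 ± 0.31 and OPR3 1.25 ± 0.19. Of 30 signalling genes 22 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 1.3e-09, adjusted p = 0.32 with an estimated correlation), and all 15 JAZ genes rose (camera adjusted p = 7.6e-15; adjusted p = 0.027 with an estimated correlation). COI1 (Sobic.003G359600) had -1.66 ± 0.13. Defence genes rose in 31 of 72 and fell in 5, 37 and 5 adjusted over the list alone (camera adjusted p = 1.0e-06, adjusted p = 0.68 with an estimated correlation); the chitinase gene (Sobic.006G132300) reached 5.24 ± 0.53. Phenylpropanoid genes rose in 23 of 39 and fell in 3, 24 and 3 adjusted over the list alone (camera adjusted p = 0.00012, adjusted p = 0.71 with an estimated correlation). CAD9 had 6.92 ± 0.53 and HCT 7.01 ± 0.37. Peroxidase and glutathione transferase genes rose in 53 of 155 and fell in 7, 53 and 8 adjusted over the list alone (camera adjusted p = 0.0014, adjusted p = 0.78 with an estimated correlation). Only 34 and 33 rose without intact 3 h replicate c and without leaf-removed 3 h replicate d. WRKY genes rose in 17 of 65 and fell in 1, 16 and 1 adjusted over the list alone (camera adjusted p = 0.027, adjusted p = 0.78 with an estimated correlation). WRKY28 had 5.48 ± 0.58. Gibberellin genes rose in 7 of 13 and fell in 1, also when adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.71 with an estimated correlation). GA2OX2 had 5.40 ± 0.61. Among the highest folds at 3 h were the alpha/beta-hydrolase Sobic.010G160033 (10.78 ± 0.77), the lectins Sobic.002G093700 (9.77 ± 0.27) and Sobic.002G093600 (8.45 ± 0.73), the RING finger gene Sobic.006G005500 (9.23 ± 0.47) and BT1 (Sobic.004G203200, 6.96 ± 0.39), which encodes a BTB and TAZ domain protein.

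Histone genes fell at 3 h, with 28 of 52 lower and none higher, 31 and 0 adjusted over the list alone, and a median of -1.42 (camera adjusted p = 3.1e-07, adjusted p = 0.78 with an estimated correlation). HIS1-3 (Sobic.010G021300), a linker histone that is stress-inducible in Arabidopsis, fell to 2.17% of the intact level (-5.53 ± 0.62). Leaf-removed 3 h replicate b is one of the libraries in which histone genes lie low, and without it 20 histone genes were lower; without all 5 such libraries 39 of 52 were. All 5 B-type cyclins fell, among them CYCB1;2 (Sobic.003G328500) at -2.07 ± 0.18 and CYCB2;4 (Sobic.006G179200) at -1.68 ± 0.12. Of 53 cell cycle genes 26 fell and 1 rose, 26 and 2 adjusted over the list alone (camera adjusted p = 2.1e-05, adjusted p = 0.093 with an estimated correlation). Of 13 MCM genes 7 were lower, with a median of -0.51; MCM4, MCM5 and MCM6 did not pass at 0.001 ± 0.13, -0.12 ± 0.13 and -0.21 ± 0.15, and ETG1 had 0.11 ± 0.14. Chromatin genes fell in 42 of 102 and rose in 4, 43 and 5 adjusted over the list alone (camera adjusted p = 1.6e-06, adjusted p = 0.71 with an estimated correlation). CMT3 had -2.34 ± 0.18, the jumonji factor -2.17 ± 0.16 and AGO4 -1.66 ± 0.15. Cytosolic ribosomal protein genes rose in 88 of 289 and fell in 9, 87 and 9 adjusted over the list alone (camera adjusted p = 2.9e-05, adjusted p = 0.78 with an estimated correlation), for example L36e (Sobic.003G351000) at 2.005 ± 0.14. These were 150 and 17 of 288 without the 5 libraries.

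The 4 dormancy-associated genes fell at 3 h, also when adjusted over the list alone. Sobic.001G191200 stood at 34.6 ± 8.36 CPM in leaf-removed and 239 ± 24.6 in intact buds (mean ± SD, n = 3; log2 fold change -2.79 ± 0.29, adjusted p = 2.7e-06). Sobic.001G377000 had -2.67 ± 0.27, Sobic.002G213800 -1.60 ± 0.33 and Sobic.007G148200 -1.49 ± 0.22. Abscisic acid response genes were now split, with 16 of 83 higher and 15 lower, 17 and 15 adjusted over the list alone (camera adjusted p = 0.54, adjusted p = 0.97 with an estimated correlation). The phosphatase genes HAI2 (Sobic.009G161800) and HAB1 fell, at -3.83 ± 0.67 and -1.21 ± 0.16, while the dehydrin stayed up at 2.69 ± 0.22. For the metabolism of the hormone 4 of 9 genes were higher and none lower, also when adjusted over the list alone, and the median (-0.29) and mean (-0.11) pointed the other way (camera adjusted p = 0.78, adjusted p = 0.97 with an estimated correlation). CYP707A4 stayed up at 2.05 ± 0.25, ZEP had 0.54 ± 0.12, and the NCED9 genes did not pass, with -1.21 ± 0.70 for Sobic.001G155300 and 2 reads against 21 for Sobic.002G037400. CCD1 (Sobic.001G509200) and CCD4 (Sobic.004G268500) had 0.69 ± 0.25 and 1.81 ± 0.66. Each of these calls was lost when any of 5 of the 6 libraries was left out (adjusted p up to 0.14 and 0.18) and under the replicate block (adjusted p = 0.089 and 0.088). Neither BRANCHED1 gene passed, at -0.11 ± 0.18 and 0.12 ± 0.57. Of the branching list 3 of 12 were higher and 2 lower, also when adjusted over the list alone, with a median of -0.13 and a mean of 0.05 (camera adjusted p = 0.94, adjusted p = 0.98 with an estimated correlation). Among the lowest folds at 3 h were those of PAP3 (Sobic.001G442300), a purple acid phosphatase, at -6.73 ± 0.44 and the phosphate starvation gene PS3 (Sobic.006G173000) at -6.26 ± 0.51.

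Several lists called at 1 h gave no call at 3 h. Cytokinin genes were higher in 3 of 24 and lower in 2, also when adjusted over the list alone (camera adjusted p = 0.76, adjusted p = 0.97 with an estimated correlation). ARR3 had 0.49 ± 0.27 and CKX1 was still lower at -2.60 ± 0.21. Calcium and touch genes were higher in 16 of 71 and lower in 9 (camera adjusted p = 0.65, adjusted p = 0.97 with an estimated correlation). For sugar use genes these were 11 and 8 of 52 (camera adjusted p = 0.65, adjusted p = 0.97 with an estimated correlation). They were 5 and 2 of 17 for aquaporins (camera adjusted p = 0.094, adjusted p = 0.87 with an estimated correlation). Of 35 secondary wall genes 9 and 2 differed (camera adjusted p = 0.084, adjusted p = 0.84 with an estimated correlation). Of 12 clock genes 4 and 2 did (camera adjusted p = 0.89, adjusted p = 0.97 with an estimated correlation). Adjusted over the list alone the counts of these 5 lists were 16 and 9, 11 and 9, 5 and 3, 9 and 2, and 4 and 3. CWINV2 stayed up at 2.90 ± 0.31, and GIGANTEA (GI, Sobic.003G040900), a clock gene, had -0.91 ± 0.11. With library totals as scaling the median at 3 h turned from 0.06 to -0.06 for abscisic acid response, from 0.02 to -0.11 for calcium and touch, from 0.03 to -0.09 for C4 enzyme and from 0.04 to -0.09 for clock genes. The counts became 7 higher and 10 lower for sugar use, 3 higher and 4 lower for cytokinin, 19 higher and 21 lower for auxin response and 23 higher and 33 lower for heat shock genes. The early light-induced gene Sobic.002G052000 was still at 3.10 ± 0.51, and 2 of 2 such genes were higher. Of the ACC oxidases 2 of 4 fell, also when adjusted over the list alone. ACO4 (Sobic.002G221900) had -2.41 ± 0.34. No list call was made for auxin response (20 higher and 14 lower of 81; 23 and 15 adjusted over the list alone; median -0.07, mean 0.16; adjusted p = 0.85) or auxin transport (3 and 1 of 19; 2 and 1 over the list alone; adjusted p = 0.59). Nor was one made for heat shock (26 and 21 of 166; the same over the list alone; adjusted p = 0.78), wall loosening (11 and 5 of 55; 8 and 5 over the list alone; adjusted p = 0.89) or flavonoid (6 and 1 of 17; 7 and 1 over the list alone; adjusted p = 0.054). The same held for meristem (3 and 0 of 16; the same over the list alone; adjusted p = 0.40) and carbon starvation genes (3 and 6 of 15; the same over the list alone; adjusted p = 0.081). Without the 5 libraries the counts at 3 h were 11 and 2 of 19 for auxin transport, 30 and 18 of 84 for auxin response (median 0.16), 18 and 8 of 56 for wall loosening (median 0.16), 34 and 42 of 167 for heat shock, 8 and 2 of 24 for cytokinin, 18 and 12 of 52 for sugar use and 2 and 2 of 13 for branching genes (median 0.08).

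Fold changes at 6 h correlated with those at 3 h across genes (Pearson r = 0.756). The effect differed between these times for 710 genes, a count for which chance was not excluded. Of the ribosomal protein, jasmonate, defence and flavonoid genes more were higher than lower at 6 h, and 7 of 13 MCM genes of DNA replication stood above intact buds. Of 15 genes on the carbon starvation list 9 fell and 1 rose. The list calls on these groups at 6 h were lost with an estimated correlation (adjusted p = 0.093 to 0.83). The dormancy-associated genes stayed low.

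Of 289 cytosolic ribosomal protein genes 155 rose and 4 fell at 6 h, 171 and 8 adjusted over the list alone, with a median of 0.53 (camera adjusted p = 1.1e-12, adjusted p = 0.64 with an estimated correlation); L36e had 1.82 ± 0.14. Cell cycle genes were split, 13 of 53 higher and 9 lower, 13 and 10 adjusted over the list alone, with a median of -0.05 and a mean of 0.02 (camera adjusted p = 0.89, adjusted p = 0.97 with an estimated correlation). With library totals as scaling cell cycle genes became 10 higher and 17 lower. Within them 7 of 13 MCM genes were higher and 1 lower, for example MCM4 at 0.80 ± 0.13 (adjusted p = 0.00018) and MCM5 at 0.70 ± 0.13, while 3 of 5 B-type cyclins were lower. CYCB1;2 had -0.85 ± 0.17. Histone genes gave no list call, 2 of 52 higher and 3 lower, 0 and 2 adjusted over the list alone, with a median of 0.13 and a mean of -0.08 (camera adjusted p = 0.78, adjusted p = 0.97 with an estimated correlation), where library totals gave a median of -0.07, although HIS1-3 stayed at -4.80 ± 0.59. Without the 5 libraries, of which 2 are in this comparison, 13 histone genes were higher and 9 lower, and of the cell cycle genes 14 and 15. Chromatin genes were lower in 25 of 102 and higher in 13, also when adjusted over the list alone (camera adjusted p = 0.40, adjusted p = 0.97 with an estimated correlation). DDM1, CMT3 and the jumonji factor did not pass at 0.24 ± 0.10, 0.003 ± 0.17 and -0.06 ± 0.15.

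Jasmonate biosynthesis genes rose in 12 of 25 and fell in 1 at 6 h, 14 and 1 adjusted over the list alone (camera adjusted p = 0.00054, adjusted p = 0.70 with an estimated correlation). Signalling genes rose in 20 of 30 and fell in 2, 21 and 4 adjusted over the list alone (camera adjusted p = 3.1e-07, adjusted p = 0.44 with an estimated correlation). JAZ genes rose in 14 of 15 (camera adjusted p = 1.3e-12; adjusted p = 0.027 with an estimated correlation). LOX1 (Sobic.003G385500) had 2.94 ± 0.31, and the call on the second LOX1 gene (Sobic.001G125700, 1.25 ± 0.41) was lost without either intact replicate a or d or leaf-removed replicate b (adjusted p = 0.073, 0.080 and 0.12). Defence genes rose in 28 of 72 and fell in 6, 30 and 9 adjusted over the list alone (camera adjusted p = 0.0028, adjusted p = 0.83 with an estimated correlation), with the chitinase gene at 5.35 ± 0.52. Phenylpropanoid genes rose in 14 of 39 and fell in 4, 17 and 4 adjusted over the list alone (camera adjusted p = 0.019, adjusted p = 0.87 with an estimated correlation). HCT had 7.70 ± 0.40. Peroxidase and glutathione transferase genes rose in 41 of 155 and fell in 7, 40 and 7 adjusted over the list alone (camera adjusted p = 0.028, adjusted p = 0.90 with an estimated correlation). GSTL3 had 3.15 ± 0.13. Flavonoid genes rose in 7 of 17 and fell in 1, also when adjusted over the list alone (camera adjusted p = 0.019, adjusted p = 0.64 with an estimated correlation). The pigment pathway genes DFR (Sobic.003G231000) and F3H (Sobic.006G254000) reached 5.07 ± 0.74 and 4.87 ± 0.63, from 4 and 8 reads in the intact group. DFR at 1 h and 3 h (1.80 ± 0.57 and 1.84 ± 0.60) lost its call without single libraries (adjusted p up to 0.062 and 0.098). The lectin Sobic.002G093600 and the hydrolase Sobic.010G159900 had high folds at 9.02 ± 0.80 and 8.70 ± 0.90.

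The 4 dormancy-associated genes were lower at 6 h, also when adjusted over the list alone, at -2.74 ± 0.34 (Sobic.002G213800), -2.61 ± 0.27 (Sobic.001G377000), -2.52 ± 0.29 (Sobic.001G191200) and -1.18 ± 0.22 (Sobic.007G148200). Genes linked to carbon starvation fell in 9 of 15 and rose in 1, 10 and 1 adjusted over the list alone (camera adjusted p = 0.002, adjusted p = 0.093 with an estimated correlation). ASN1 had -3.12 ± 0.47 and SEN1/DIN1 -0.74 ± 0.23. That list also holds phosphate starvation genes, among them PS3 (Sobic.006G173000) at -6.04 ± 0.53 and PS3 (Sobic.007G045500) at -1.61 ± 0.18. The call on SEN1/DIN1 was lost when any of 4 of the 6 libraries was left out, intact replicates c and d and leaf-removed replicates a and b (adjusted p = 0.067, 0.12, 0.068 and 0.053). Other low folds were PAP3 at -5.35 ± 0.42, the organ-size gene ARGOS (Sobic.006G092500) at -4.82 ± 0.65, the raffinose-metabolism gene SIP2 (Sobic.002G075800) at -4.70 ± 0.51 and the wall enzyme gene XTH25 (Sobic.010G246700) at -2.45 ± 0.34; the expansin gene EXPB4 (Sobic.004G294300) rose by 3.54 ± 0.37. Abscisic acid response genes were lower in 17 of 83 and higher in 9, also when adjusted over the list alone, with a median of -0.10 and a mean of 0.37 (camera adjusted p = 0.62, adjusted p = 0.97 with an estimated correlation). HAI2 had -3.70 ± 0.64, CYP707A4 was at -0.14 ± 0.25, and of the metabolism list 2 of 9 were higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.78, adjusted p = 0.97 with an estimated correlation). CKX1 stayed low at -3.87 ± 0.22 and GH3.2 had -2.80 ± 0.60. Neither BRANCHED1 gene passed (-0.19 ± 0.18 and -0.36 ± 0.58), MAX2 had -0.44 ± 0.15, and 4 of 12 branching genes were lower and none higher, also when adjusted over the list alone (camera adjusted p = 0.32, adjusted p = 0.97 with an estimated correlation). The MAX2 call was lost when any of 4 of the 6 libraries was left out (adjusted p up to 0.18) and under the replicate block (adjusted p = 0.060).

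The remaining lists gave no call at 6 h. These were WRKY (8 higher and 6 lower of 65; 7 and 6 adjusted over the list alone; adjusted p = 0.54), calcium and touch (10 and 13 of 71; the same over the list alone; adjusted p = 0.65), sugar use (9 and 4 of 52; 8 and 4 over the list alone; median -0.11, mean 0.05; adjusted p = 0.88) and secondary wall genes (3 and 3 of 35; 2 and 3 over the list alone; adjusted p = 0.89). Among hormone lists they were auxin response (7 and 18 of 81; 5 and 15 over the list alone; adjusted p = 0.073), auxin transport (3 and 3 of 19; 3 and 4 over the list alone; adjusted p = 0.54), cytokinin (2 and 3 of 24; 1 and 2 over the list alone; adjusted p = 0.37) and gibberellin (5 and 2 of 13; 5 and 3 over the list alone; adjusted p = 0.40). The others were heat shock (33 and 35 of 166; 34 and 36 over the list alone; adjusted p = 0.78), wall loosening (11 and 9 of 55; the same over the list alone; median -0.24, mean 0.10; adjusted p = 0.98), aquaporins (3 and 1 of 17; the same over the list alone; adjusted p = 0.32), clock (2 and 2 of 12; 2 and 3 over the list alone; adjusted p = 0.65) and meristem genes (1 and 3 of 16; the same over the list alone; adjusted p = 0.62). With library totals as scaling the median at 6 h turned from 0.09 to -0.11 for gibberellin and from 0.13 to -0.05 for WRKY genes. The counts became 6 higher and 10 lower for sugar use, 11 higher and 14 lower for wall loosening, 8 higher and 10 lower for C4 enzyme, 2 higher and 4 lower for cuticle and 2 higher and 4 lower for secondary wall genes. Leaving out the 5 libraries gave 3 and 7 of 19 for auxin transport, 8 and 9 of 52 for sugar use, 12 and 13 of 56 for wall loosening and 2 and 3 of 9 for abscisic acid metabolism. Both early light-induced genes were higher at 6 h, Sobic.002G052000 at 3.56 ± 0.53, and 2 of 4 ACC oxidase genes were lower.

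**Figure D3:**
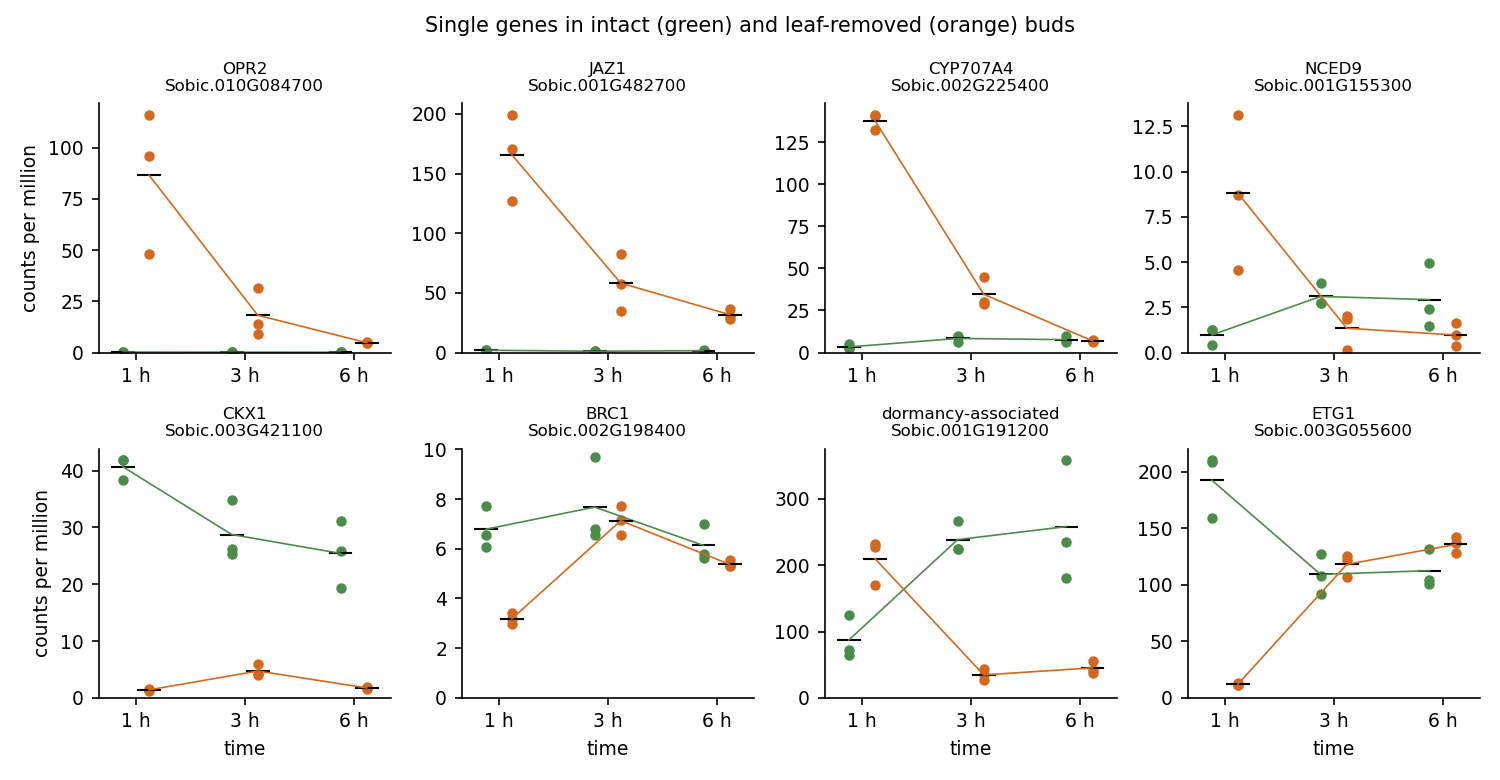
CPM of 8 genes in each library (points) with group means (black bars, joined by lines), for intact (green) and leaf-removed (orange) buds at 1, 3 and 6 h. CYP707A4 rose at 1 h and was at the intact level at 6 h, and the dormancy-associated gene was above intact buds at 1 h and below them at 3 h and 6 h.

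How the response changed between times was tested directly. The effect of leaf removal differed between 1 h and 3 h for 5820 genes, between 1 h and 6 h for 8330 and between 3 h and 6 h for 710. For the dormancy-associated genes the effect at 3 h lay -4.06 (Sobic.001G191200, adjusted p = 3.1e-06), -3.49 (Sobic.001G377000), -3.71 (Sobic.002G213800) and -2.38 (Sobic.007G148200) log2 units from that at 1 h. For MCM4 the effect rose by 3.37 from 1 h to 3 h (adjusted p = 4.2e-08), and for CYCB1;2 it changed by -2.03 (adjusted p = 1.8e-05). As lists, cell cycle genes rose relative to intact buds from 3 h to 6 h (median difference 0.59, camera adjusted p = 7.7e-10; adjusted p = 0.0095 with an estimated correlation, and 0.057 with it under the replicate block). Histone genes fell from 1 h to 3 h (median -1.55, camera adjusted p = 5.5e-06; adjusted p = 0.74 with an estimated correlation). Ribosomal protein genes rose from 1 h to 6 h (median 0.58, camera adjusted p = 2.8e-09; adjusted p = 0.74 with an estimated correlation). Cytokinin genes rose from 1 h to 3 h (median 1.89, camera adjusted p = 0.00074; adjusted p = 0.71 with an estimated correlation). Abscisic acid response genes fell from 1 h to 6 h (median -1.52, camera adjusted p = 8.1e-07; adjusted p = 0.71 with an estimated correlation). The 710 genes for 3 h against 6 h became 3809 without the 5 libraries that deviate alike and 1410 with DESeq2. They became 448 under the replicate block and 447 to 1073 with single libraries left out.

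**Figure D4:**
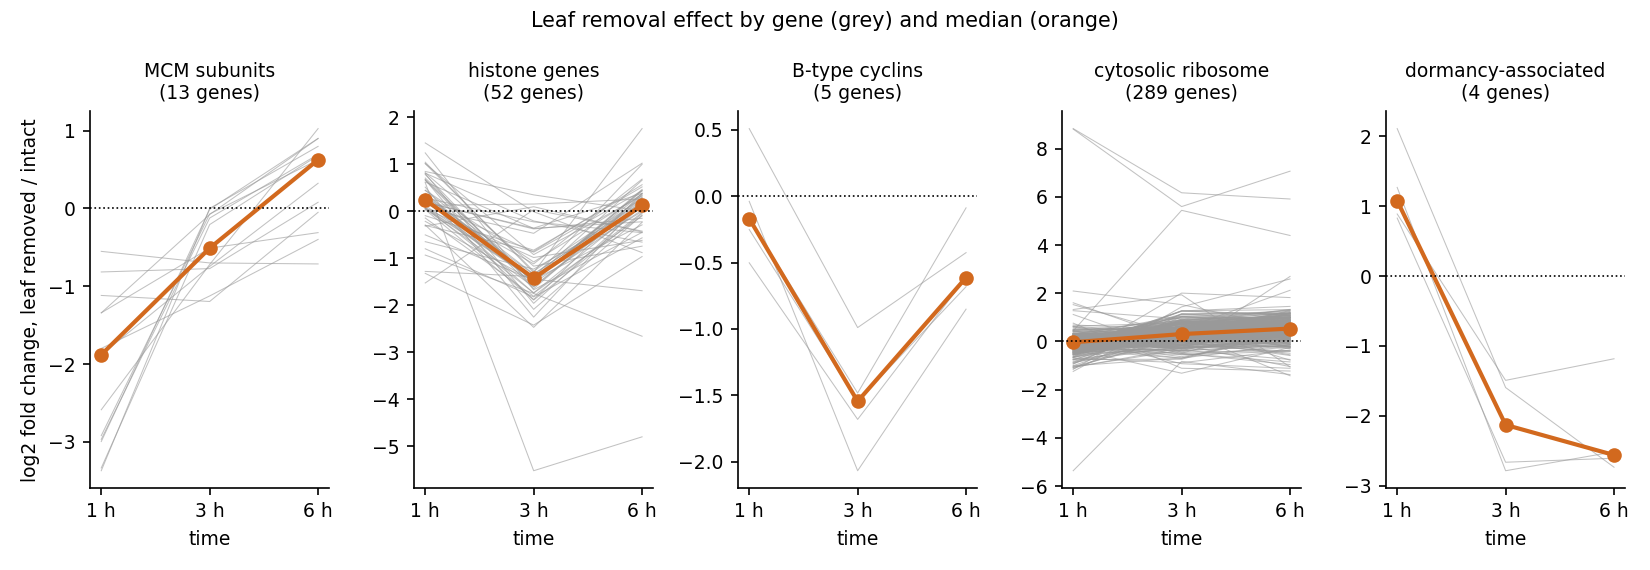
Log2 fold change of leaf-removed over intact buds at 1, 3 and 6 h for each gene (grey) and the median (orange) of 5 gene groups, each with its own vertical scale. The MCM median went from -1.88 to -0.51 and 0.63, and the histone median from 0.25 to -1.42 and 0.13, with library totals as scaling giving -0.0022 and -0.07 for the first and last histone value.

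The calls of the 3 times overlapped. Of the genes called at both 1 h and 3 h 2339 were higher and 1713 lower at both, where independent lists of these sizes would share 965 and 850.1, and 886 changed in opposite directions, against 1813. At 3 h and 6 h 2482 were higher and 2039 lower at both, against 702 and 562 for independent lists, and 130 were opposite, against 1256. At 1 h and 6 h 1625 and 1178 were shared, against 979 and 837, and 1686 were opposite, against 1812. In all, 1462 genes were higher and 877 lower at every time. The intact libraries of each time are separate, so these comparisons share no library. They do share one fit and its estimate of the spread, so the values for independent lists are a reference and not a test.

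Intact buds also changed over the day. Over the 3 times 2125 genes differed in intact buds, with 1464 between 1 h and 3 h, 2339 between 1 h and 6 h and 196 between 3 h and 6 h in the pairwise tests. The 2125 became 1198 under the replicate block, 3559 with DESeq2 and 4366 without the 5 libraries that deviate alike. With single libraries left out they were 1235 to 1969. The clock gene GI rose by 2.85 log2 units from 1 h to 6 h (adjusted p = 6.7e-10) and TOC1 by 1.90 (adjusted p = 2.3e-05). In intact buds 3 of the 4 dormancy-associated genes rose from 1 h to 3 h, Sobic.001G191200 by 1.45 (adjusted p = 0.0055), Sobic.001G377000 by 1.06 (adjusted p = 0.019) and Sobic.002G213800 by 1.39 (adjusted p = 0.02), and Sobic.007G148200 did not pass at 0.70 (adjusted p = 0.063). In leaf-removed buds Sobic.001G191200 changed by -2.60 (adjusted p = 4.2e-06). MCM4 changed by -0.75 from 1 h to 3 h in intact buds (adjusted p = 0.0025). Time since treatment and time of day rise together in this design.

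The deposited table also holds the authors' own test between leaf-removed and intact buds at each time. Their adjusted p was under 0.05 for 3406 genes at 1 h, 1783 at 3 h and 1797 at 6 h, of which 3394, 1776 and 1785 were also called here, all in the same direction. A further 7290, 5644 and 5636 genes were called only here. On simulated changes in these libraries the test found 44.8% to 46.3% of 2-fold changes between treatments and 83.3% to 90.9% of 4-fold changes. The simulation changed only 66 or 67 genes per fold size, all of them well covered by reads. It held no deviation shared by libraries. With so few changed genes the adjusted threshold is stricter than in the data, so these rates do not give the share of real changes found.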

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

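The correlations with intron share and depth, the dormancy gene change within leaf-removed buds, the histone median without 5 libraries, the other scalings of MCM and histone genes, the splits within single times, the test of intron reads and every setting with unique reads or without 5 libraries were tests chosen only after the result was seen. The differences between times were planned. Each named gene or list in the next paragraphs is given only for the pair of times with its smallest adjusted p. The same gene or list can also differ between other times, so no paragraph is complete for its pair.

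The log2 effect of leaf removal was lower at 6 h than at 1 h by these differences: -7.37 (Sobic.002G037400), -6.05 (Sobic.010G105000), -5.94 (Sobic.006G092500), -5.53 (Sobic.002G225400), -5.13 (Sobic.001G406800), -4.85 (Sobic.002G213800), -4.82 (Sobic.009G161800), -4.76 (Sobic.001G155300), -4.35 (Sobic.001G420100), -4.10 (Sobic.009G247300), -4.01 (Sobic.001G125700), -4.01 (Sobic.002G075800), -3.99 (Sobic.009G196300), -3.93 (Sobic.010G270300), -3.88 (Sobic.009G213000), -3.82 (Sobic.010G084700), -3.79 (Sobic.001G191200), -3.56 (Sobic.009G085900), -3.44 (Sobic.001G377000), -3.36 (Sobic.001G149500), -3.19 (Sobic.010G246700), -2.99 (Sobic.004G313100), -2.38 (Sobic.003G313800), -2.25 (Sobic.003G296000), -2.19 (Sobic.007G135700), -2.13 (Sobic.007G151100), -2.04 (Sobic.001G482700), -1.89 (Sobic.009G257300), -1.87 (Sobic.006G150800), -1.72 (Sobic.002G306000), -1.48 (Sobic.010G043000), -1.40 (Sobic.001G094400), -1.34 (Sobic.009G195000), -1.34 (Sobic.002G424350), -1.25 (Sobic.006G097500), -0.95 (Sobic.003G359600), -0.77 (Sobic.004G216700) and -0.75 (Sobic.009G249900), with adjusted p up to 0.046. The log2 effect of leaf removal was higher at 6 h than at 1 h by these differences: 4.27 (Sobic.003G055600), 4.21 (Sobic.006G254000), 4.17 (Sobic.003G183700), 4.02 (Sobic.009G087000), 3.66 (Sobic.004G331600), 3.51 (Sobic.001G175000), 3.27 (Sobic.003G231000), 2.81 (Sobic.006G132300), 2.73 (Sobic.001G169800), 2.47 (Sobic.003G351000), 2.42 (Sobic.002G021200), 2.08 (Sobic.004G294300) and 1.26 (Sobic.002G374100), with adjusted p up to 0.012.

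The log2 effect of leaf removal was lower at 3 h than at 1 h by these differences: -6.14 (Sobic.010G021300), -4.13 (Sobic.001G442300), -3.21 (Sobic.002G052100), -2.76 (Sobic.006G173000), -2.38 (Sobic.007G148200), -2.03 (Sobic.003G328500), -1.23 (Sobic.007G045500), -1.18 (Sobic.006G179200) and -0.84 (Sobic.003G040900), with adjusted p up to 0.02. The log2 effect of leaf removal was higher at 3 h than at 1 h by these differences: 4.34 (Sobic.004G178000), 4.05 (Sobic.001G331200), 3.58 (Sobic.005G025900), 3.19 (Sobic.004G203200), 2.27 (Sobic.003G421100), 1.33 (Sobic.002G093700), 0.98 (Sobic.002G198400) and 0.89 (Sobic.004G037800), with adjusted p up to 0.0094.

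The log2 effect of leaf removal was higher at 6 h than at 3 h by these differences: 2.35 (Sobic.006G214000) and 0.81 (Sobic.003G129500), with adjusted p up to 0.041.

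As lists, the median difference between 1 h and 6 h was -1.07 (jasmonate biosynthesis), -1.52 (abscisic acid response), -0.82 (calcium and touch), -1.19 (phenylpropanoid), -0.78 (clock), -1.001 (WRKY), -0.75 (sugar use), -1.67 (carbon starvation), 0.58 (cytosolic ribosomal protein) and -0.86 (secondary wall) (camera adjusted p up to 0.049; with an estimated correlation all were lost, at 0.38 to 0.74). As lists, the median difference between 1 h and 3 h was -1.21 (abscisic acid metabolism) and 1.89 (cytokinin) (camera adjusted p up to 0.042, and with an estimated correlation all were lost, at 0.38 to 0.71). Lists given here under another pair were also called for 1 h and 3 h. Examples were histones (-1.55, camera adjusted p = 5.5e-06) and abscisic acid response (-1.01, camera adjusted p = 3.1e-06). Both were lost with an estimated correlation (adjusted p = 0.74 and 0.72). As lists, the median difference between 3 h and 6 h was -0.42 (jasmonate signalling), -0.34 (auxin response), -1.36 (gibberellin), 0.59 (cell cycle), 1.48 (histones), 0.23 (chromatin), 0.19 (photosynthesis), -0.47 (defence) and -0.47 (meristem) (camera adjusted p up to 0.035; with an estimated correlation all but cell cycle were lost, at 0.74 to 0.78).

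Of these values, that of Sobic.002G037400 rests on 1 read in the leaf-removed libraries at 6 h and that of Sobic.002G052100 on 2 reads in the intact libraries at 1 h, so their sizes depend on the fit.

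With an estimated correlation the cell cycle difference between 3 h and 6 h kept an adjusted p of 0.0095 (0.057 with the replicate block as well), and for histone genes, of which no single member passed that test, it was 0.74.

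Reads in introns, which the main comparisons did not use, also differed. At 1, 3 and 6 h 3551, 1894 and 1574 of 14725 genes were called from intron reads, of which 2967, 1261 and 1050 were also called from exon reads, 2948, 1236 and 1017 of them in the same direction.

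The number of genes whose effect differed was 5820 between 1 h and 3 h, 8330 between 1 h and 6 h and 710 between 3 h and 6 h. Of 60 splits of the libraries drawn for each, the real split alone (1 of 60) gave as many for the first and second. The highest other gave 4511 and 6806. Splits that mixed the times of the leaf-removed libraries gave at most 80 and 26 genes. They speak to change with time in leaf-removed buds and not to a difference of the effect. Only 5 and 3 of the other splits kept those times together, the highest others among them. That is too few for a share under 0.05, so that chance cannot be excluded for either difference. For 3 h against 6 h 5 of 60 splits gave as many, the highest other 1298 and at most 3 in splits that mixed those times, so that chance cannot be excluded. The 4 others as large kept the leaf-removed libraries grouped by time and regrouped the intact ones. They thus still hold the change of leaf-removed buds between 3 h and 6 h. For that change 3132 genes were called, against 196 in intact buds. For intact buds over time the real split with 2125 genes was 1 of 60, the lowest share this draw allows, and the highest other 1485. This argues against chance for the 3 times as a whole, without correction for the other comparisons. The highest others (1485, 1457 and 1294 genes) kept the libraries of 1 h together. The count thus speaks mainly to 1 h against the later times, and chance cannot be excluded for a change between 3 h and 6 h. For leaf removal at 1, 3 and 6 h the 10 splits of 3 against 3 are too few for a share under 0.05, with real values of 10684, 7420 and 7421, the real split being 1 of 10 in each, and the highest other 0.

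In 5 libraries of 5 groups the values deviated alike from their group. More unspliced RNA is a candidate explanation that the tables leave open: the score correlated with the intron share (Pearson r = 0.937, permutation p = 9.4e-04, adjusted p = 0.0019, Spearman rho = 0.839, permutation p = 0.0054, r = 0.912 without the 2 farthest libraries). Depth cannot be told apart from it on these values (r = -0.0176, permutation p = 0.957, rho = 0.170, permutation p = 0.443), because r was 0.546 without the 2 farthest libraries. Gene length cannot be told apart either, since 74.1% of the sum of squares stayed after removing a length trend, between the limits set for the test. No biological explanation was tested.

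The dormancy-associated genes lay above intact buds at 1 h and below them at 3 h and 6 h. Scaling is argued against by the lowest median at 1 h over other scalings, 0.83, and the 5 libraries by an adjusted p of at most 7.3e-05 for the difference without them. Shared reads are argued against by 100% unique reads in these genes, so that the p with unique reads (3.7e-05) is no separate test. A change in intact buds alone is argued against by a median change of -2.38 from 1 h to 3 h in leaf-removed buds. That leaf removal first raises and then lowers these genes may be proposed as a hypothesis, found and tested on the same data, with time of day untested.

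MCM genes were lowest against intact buds at 1 h and histone genes at 3 h. The 5 libraries are argued against as the whole cause by a histone median of -1.05 without them. For the histone genes at 3 h gene length is argued against by sets of matched genes, whose lowest median was -0.079, and it was not tested for the MCM genes. Scaling is argued against by a highest median of -1.39. A staggered fall of replication and histone genes after leaf removal may be proposed as a hypothesis, found and tested on the same data, with base composition and time of day untested.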

How the results depend on the processing

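Unique reads, the fits without the 5 libraries that deviate alike and the intron share as a covariate were chosen only after the result was seen. Of 213 called values of 87 named genes 202 kept their call and direction under every alternative run for single genes, each library left out in turn included. The others run were DESeq2, its size factors, the replicate block over all times, unique reads and the fit without the 5 libraries. Library totals and the remaining alternatives were not run for single genes. Many named genes were chosen for high folds or small p in these data, which favours a high share kept. The counts at 1, 3 and 6 h ranged from 9360 to 10693, from 5552 to 7387 and from 5865 to 6809 with each library left out in turn, which leaves 2 libraries in that group. Library totals changed the higher and lower counts to 4161 and 7252, 3030 and 4427, and 2600 and 5261, from 5423 and 5261, 3889 and 3531, and 3943 and 3478, as the construction of that scaling shows.

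For the difference between 3 h and 6 h (710 genes) DESeq2 gave 1410, the replicate block 448, the fit without the 5 libraries 3809 and the intron covariate 1971; leaving out single libraries gave 447 (leaf-removed 6 h b) to 1073 (leaf-removed 3 h b), with 450 without intact 3 h c, 451 and 449 without leaf-removed 3 h c and d and 464 without leaf-removed 6 h d. For intact buds over time (2125) the same settings gave 3559, 1198, 4366 and 4655, and 1235 (without intact 1 h c) to 1969 (without intact 6 h d). The replicate block within each time gave 6340 at 1 h, 1572 at 3 h and 8611 at 6 h, from 10684, 7420 and 7421. It kept only libraries whose letter occurs in both groups: b, c and d at 1 h, b and c at 3 h, a and d at 6 h. The fits at 3 h and 6 h thus dropped a library per group and left few residual degrees of freedom. How much of each change comes from this and how much from the block was not tested. A minimum of 2-fold gave, by construction, 5749, 3334 and 2990 at the 3 times, 3494, 444 and 5517 for 1 h against 3 h, 3 h against 6 h and 1 h against 6 h, and for the overlap of calls between 1 h and 3 h 1930, the overlap of calls between 3 h and 6 h 1738 and the overlap of calls between 1 h and 6 h 1243. Of 35 list calls 1 stayed with an estimated correlation, while fry called 45 in one direction and 88 in either. The fry test asks whether members changed at all and not whether they changed more than other genes. With so many genes called at each time, its calls do not offset those lost.

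Values that reversed had not been called. CCD1 (Sobic.010G050300) at 6 h was 0.021 with DESeq2 size factors, 0.019 with DESeq2, 0.30 without the 5 libraries, 0.14 without leaf-removed 6 h a, and -0.20 to 0.37 over single libraries. BRANCHED1 (Sobic.007G135700) at 3 h was -0.18 under the replicate block and -0.53 to 0.55 over single libraries, and at 6 h -0.65 to 0.41. CCD4 (Sobic.004G268500) at 6 h was 0.047 without the 5 libraries, 0.15 without intact 6 h c, and -0.52 to 0.23 over single libraries. BRANCHED1 (Sobic.002G198400) at 3 h was -0.20 to 0.095. The cause was not tested. In the simulated data, with the limits given above, 8.96% to 11.9% of 1.5-fold changes were found, and 17.9% to 22.4% of 2-fold differences between times.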

Other observations

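The groups below were chosen only after the result was seen, apart from their annotation. Mannose-binding lectin genes, a family of sugar-binding defence proteins, were higher in 7 of 9 at 1 h and 3 h and in 5 at 6 h, where 1 was lower, with medians of 4.24, 4.84 and 3.40. Genes of ribosomal RNA processing and the nucleolus were lower in 13 of 25 at 1 h with 2 higher, and higher in 9 and 11 with 4 and 5 lower at 3 h and 6 h. CYP94 genes, whose Arabidopsis counterparts break down the active jasmonate conjugate, were higher in 4 of 5 at each time.

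Narrower lists, adjusted among themselves only, gave these results. Mitotic cyclins were lower in 9 of 10 at 3 h (camera adjusted p = 4.7e-07, and adjusted p = 0.027 with an estimated correlation). The narrow cell cycle list was lower in 27 and 21 of 37 at 1 h and 3 h (camera adjusted p = 9.7e-11, adjusted p = 0.019 with an estimated correlation; camera adjusted p = 9.7e-07, adjusted p = 0.027 with an estimated correlation), and the narrow histone list in 28 of 49 at 3 h (camera adjusted p = 1.6e-08, adjusted p = 0.68 with an estimated correlation). Small heat shock proteins were higher in 12 of 35 and lower in 5 at 1 h (camera adjusted p = 0.052, adjusted p = 0.97 with an estimated correlation), and light-harvesting genes higher in 1 of 19 and lower in 4 at 3 h (camera adjusted p = 0.15, adjusted p = 1.00 with an estimated correlation).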
